A study of Homo sapiens and Mus musculus with 160 samples.

How the data were processed

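RNA half-lives were measured by subcellular TimeLapse-seq in human K562 cells, a chronic myelogenous leukaemia line with erythroid features, and in mouse NIH-3T3 cells, an embryonic fibroblast line. Cells were given 4-thiouridine, a uridine analog that is built into new RNA, for 0, 15, 30, 60 or 120 minutes, and TimeLapse chemistry then recoded the analog so that new transcripts carried T-to-C mismatches in the reads. RNA was taken from 5 fractions: chromatin, nucleus, cytoplasm, polysomes and whole cells. The series holds 160 samples, of which 100 untreated ones (50 per cell line, in 2 replicate time courses of 5 labelling times and 5 fractions) stand behind the values used here. The remaining 60 samples, from cells with shRNAs against 6 targets or with a scramble shRNA, were not analysed here. Libraries were made with a stranded total RNA kit, and the submitters' notes name cutadapt 2.5 for trimming and STAR 2.7.0a for alignment to the hg38 and mm10 builds.

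The deposited values were 4 tables, 1 per cell line and replicate, each the outcome of a Bayesian fit of the kinetic rates of 1 time course. Per the labels, half-lives are given by the authors in minutes (unit: other, an absolute time), with a posterior mode, a posterior mean and a 95% credible interval per gene, and they were not normalized between tables. The deposited Bayes factors are ratios of 2 model likelihoods without a unit (unit: other), which compare a model with nuclear degradation against one without it. The tables also hold the authors' own yes or no call of nuclear degradation, which equalled a Bayes factor of at least 100 in both replicates for every assessed gene. The 6 kinds of half-life compared were those on chromatin, in the nucleus, for nuclear export (from nuclear RNA released from chromatin), in the cytoplasm, for loading onto polysomes, and in the whole cell. Values carry 2 significant digits and are bounded at 6900 minutes, so differences that involve that bound are limits of the fit rather than measured sizes. Low values also recurred, such as 0.27 minutes for H3C14 on chromatin in both K562 replicates. Whether the fit has a lower limit was not stated. Apart from unlabelled samples, labelling times ran from 15 to 120 minutes. Half-lives far below or far above that range lie outside the times sampled and rest more on the fitted model. The export half-life comes from the authors' model without nuclear degradation, so for genes with the degradation call a short export half-life may reflect decay in the nucleus. The settings and filters of the authors' fit were not stated. Numbers of reads behind each value are not part of the tables, so the depth per sample is unknown here and the authors' credible intervals were used as the measure of precision. They cover the fit's uncertainty within 1 time course only.

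A replicate was 1 table (n = 2 per line). The labels do not state whether the replicates are separate cultures, so the limma p-values between lines measure only the spread between these tables, which may be technical. The permutation and Fisher p-values are computed across genes and do not use that spread. Replicate agreement was described by the correlation of log2 half-lives across genes. Within a line, a gene was counted as slower at one step than at another when the authors' 95% credible intervals did not overlap in either replicate, in the same direction. The 2 lines were compared gene by gene with limma 3.58.1 in R 4.3.3 on log2 posterior modes of 2 tables against 2, two-sided, with genes paired by symbol ignoring case (14100 symbols), no pseudocount, no centring, and Benjamini-Hochberg adjustment within each kind of half-life. A test was called at an adjusted p under 0.05. Ratios of paired steps were compared between lines in the same way, which tests the difference itself. This comparison of ratios was added after the tables were first examined.

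The gene lists were cytosolic ribosomal proteins, mitochondrial ribosomal proteins, nuclear-encoded respiratory chain, mitochondrially encoded genes, proteasome subunits, glycolysis, translation factors, aminoacyl-tRNA synthetases, cholesterol biosynthesis, immediate early and AU-rich genes, splicing regulators, core spliceosome, snoRNA host genes, ribosome biogenesis, the ATF4 program, p53 target genes, chaperones, mitotic genes, DNA replication, nuclear RNA decay machinery, cytoplasmic mRNA decay machinery, erythroid genes, fibroblast and matrix genes, histone and DNA modifiers, RNA polymerase II and Mediator, nuclear pore and mRNA export, replication-dependent histones, and the C2H2 zinc-finger family. Membership came from textbook knowledge. These lists, the tests described in this section other than that of ratios, the rule for named genes and most alternatives were fixed before the data were examined. The tests of explanations in the closing sections, with their list of endoplasmic reticulum genes, came later. Within a line, a list's median log2 half-life (mean of both replicates) was compared with 100000 random lists of the same size by a two-sided permutation test, adjusted over all lists, half-lives and both lines, and a list was called only when both replicates placed it on the same side of the other genes. The smallest p that these permutations can give is 2e-05. Lists needed 5 genes with values. Mitochondrially encoded genes (0 in either table) and snoRNA host genes (1 in K562 and 3 in NIH-3T3) could not be tested. Between lines, lists were tested with limma's camera at its preset correlation and again with an estimated correlation. Shares of genes with the nuclear degradation call were compared by two-sided Fisher's exact test.

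Genes named in the text were chosen by rule. Per line, and for chromatin, export, cytoplasmic and whole-cell half-life, these were the longest and shortest 5 with credible intervals of at most 4-fold in both replicates. Between lines, they were the 10 largest differences each way that passed limma and whose intervals lay apart in all pairs of tables. To these were added members at either end of each called list, a fixed set of 34 landmark genes, and the genes with the highest Bayes factors or with a degradation call in both lines. Some posterior modes lay outside their own credible interval (0.233 to 4.69% of values per table and half-life), among them those of several of the shortest-lived genes. Such genes are not presented as extremes, and the shortest-lived genes given in their place, with modes inside their intervals, were chosen after the values were seen.

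For K562, spliced length, exon number, 3' UTR length and GC content were taken from the longest protein-coding transcript in GENCODE 29 (hg38). Gene length was the span of the annotated gene. Genes were matched by gene identifier, for 97.9% of 13511 genes (96.5% for 3' UTRs and 97.8% for GC content). Mouse gene structure was not analysed here. The tests were run with Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1.

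Limma, camera and the permutation test were tried on simulated data with the sizes of the real comparison. The interval counts and Fisher's exact test were not simulated. Of 100 genes changed by log2 2 among 9380, with each gene's own spread, limma recovered 0% for chromatin, and 41% of 100 for nuclear (9466 genes), 0% for export (9135), 0% for cytoplasmic (9087), 0% for polysome loading (8358) and 57% for whole-cell half-life (8913). With spreads moderated across genes these shares were 98%, 89%, 2%, 0%, 0% and 90%. With such spreads and about as many changed as unchanged genes (2344 genes at each of log2 1 and log2 2 for chromatin), they were 99.8%, 98.8%, 84.0%, 95.7%, 0% and 97.8% of changes of log2 2, with 0 to 116 false calls. Changes of log2 1 were recovered in 66.0%, 92.1%, 18.8%, 67.9%, 0% and 91.2% of genes of the last simulation. Recovery thus differed with the number of changed genes, and no simulation of single genes recovered changes in polysome loading. Camera recovered 100% of 10 shifted lists with 0 false calls. The permutation test called 99% of lists of 40 genes shifted by log2 1 and 6% of unshifted ones (12276 genes, K562 cytoplasmic half-life). Genes were simulated or drawn independently of each other, so neither result shows how these tests behave for lists of correlated genes.

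The alternatives tried were the posterior mean, narrow intervals (at most 4-fold), trimming of extreme values, a 2-fold criterion in place of intervals, centring of each table on its median, a pseudocount of 1 minute, the replicate number as a block, limma with trend and robust settings, credible intervals in place of limma, cameraPR in place of permutation (alternatives used 10000 permutations), random lists matched on interval width, other Bayes factor thresholds, the median over transcripts, and leaving out each replicate. Restricting to genes whose mode lay inside its interval, and restricting export to genes without the degradation call, were added after the data had been seen.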

Results

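The data were RNA half-lives per gene in K562 cells and NIH-3T3 fibroblasts, measured by metabolic labelling and sequencing of RNA from chromatin, nuclei, cytoplasm, polysomes and whole cells. Each of the 4 tables (2 replicates per line) listed 18165 human or 17985 mouse genes, of which 11392 to 13514 had a value for a given half-life. The labels name fractions along the path of a transcript from chromatin to polysomes, so the comparisons ask how long RNA stayed at each step, which genes were slow or fast at it, how the 2 lines differed, and which genes the authors' model placed under nuclear degradation. Values are posterior modes in minutes from the authors' fit, given for replicates 1 and 2 in that order, and intervals are the authors' 95% credible intervals. The number of reads behind each value is unknown here.

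Replicate tables were compared first. MYC, a transcription factor gene with a short-lived mRNA (hg38 chromosome 8, 127735434 to 127741434), had a whole-cell half-life in K562 of 27 minutes (interval 25 to 30) and 28 minutes (25 to 31). GAPDH, a glycolytic enzyme gene, had 1100 minutes (1100 to 1200) and 1000 minutes (950 to 1100). In NIH-3T3, Myc had 21 minutes in both replicates and Gapdh 690 minutes in both. Other values differed widely between replicates, such as the NIH-3T3 export half-lives of Fn1 (220 and 13 minutes), Actb (220 and 12) and Vim (130 and 9.1). Across genes, Spearman's rho between replicates in K562 was 0.883 for chromatin, 0.909 for nuclear, 0.911 for export, 0.812 for cytoplasmic, 0.583 for polysome loading and 0.878 for whole-cell half-life. Pearson's r was 0.736, 0.808, 0.901, 0.705, 0.506 and 0.780. In NIH-3T3 the rho values were 0.910, 0.913, 0.732, 0.833, 0.633 and 0.903, and the r values 0.805, 0.833, 0.708, 0.742, 0.530 and 0.798. These are correlations across genes, which are not independent replicates. The median fold between replicates was lowest for NIH-3T3 whole-cell half-life (1.11) and highest for K562 polysome loading (2.35). Shifts common to most genes were present too: NIH-3T3 replicate 2 lay above replicate 1 by a median log2 of 0.45 for chromatin and below it for export (median -0.55), and K562 polysome loading was higher in replicate 2 by 0.85.

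Median half-lives in K562 were 48 and 53 minutes on chromatin, 73 and 85 in the nucleus, 39 and 47 for export, 86 and 76 in the cytoplasm, 8 and 14 for polysome loading, and 210 and 200 in the whole cell. The NIH-3T3 medians were 54 and 72, 77 and 79, 41 and 28, 37 and 36, 11 and 10, and 110 and 110 minutes. Nuclear half-life made up a median of 45.2% and 51.4% of the summed nuclear and cytoplasmic half-lives of a gene in K562, and 65.5% and 67.0% in NIH-3T3.

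**Figure D1:**
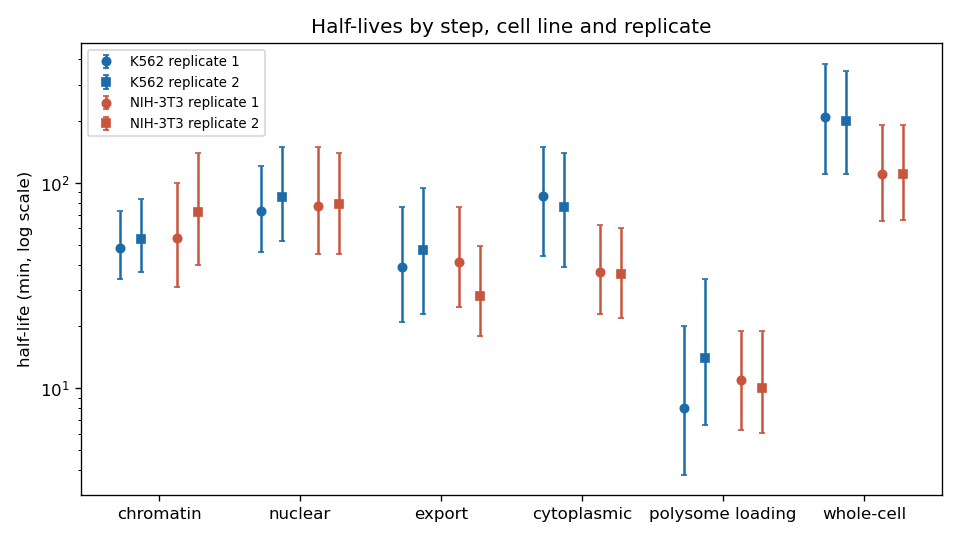
Half-lives in minutes (log scale) for the 6 steps on the horizontal axis, as the median over genes (points, circles for replicate 1 and squares for replicate 2) with the interquartile range (bars), for K562 (blue) and NIH-3T3 (red). Cytoplasmic medians of 86 and 76 minutes in K562 stand above those of 37 and 36 minutes in NIH-3T3, while nuclear medians lie between 73 and 85 minutes in all 4 tables.

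Within K562, the first comparison asked at which step a transcript spent longer. Nuclear half-life here is that of RNA in the nuclear fraction. Whether this fraction also held mRNA bound to the endoplasmic reticulum is weighed in the closing section and stays open. In both lines a long nuclear half-life therefore need not mean long residence inside the nucleus. HBG2, encoding fetal gamma globin, had a nuclear half-life of 930 (880 to 960) and 1100 minutes (1100 to 1100) and a cytoplasmic half-life of 23 (21 to 25) and 12 minutes (10 to 14). TFRC, the transferrin receptor gene, showed the same order with 210 and 210 nuclear minutes against 9.8 (8.3 to 11) and 6.2 (4.8 to 7.4) cytoplasmic minutes. HNRNPA3, an RNA-binding protein gene, had the opposite order, with 54 and 51 nuclear minutes against 440 (400 to 480) and 440 (410 to 480) in the cytoplasm. SRSF3, encoding a splicing factor, likewise had 29 and 43 minutes in the nucleus and 200 and 220 minutes in the cytoplasm. Of 12276 K562 genes, 2971 had a longer nuclear and 3245 a longer cytoplasmic half-life, with intervals apart the same way in both replicates. Replicate 1 alone gave 3335 against 4616, and replicate 2 alone 4436 against 3571, so the more frequent direction turned with the replicate. The chromatin half-life exceeded the export half-life in 3285 of 12220 genes and was shorter in 2416, and without genes called as degraded in the nucleus these were 2995 and 2217 of 10912. Cytoplasmic half-life exceeded that of polysome loading in 6214 of 11124 genes, and 27 genes had the reverse order. That last count was 153 without replicate 2 and 360 without replicate 1.

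In NIH-3T3 the same comparison was more one-sided. Fn1, the fibronectin gene, had 1100 nuclear minutes in both replicates and 1.6 (0.57 to 2.5) and 2 (0.75 to 3.2) cytoplasmic minutes. Col1a1, encoding a collagen chain, had 520 and 480 against 4 (1.7 to 5.9) and 2.3 (0.89 to 3.7), and Actb, the cytoskeletal actin gene, 550 and 510 against 6.8 and 6.5. Srsf3 ran the other way, with 23 and 22 nuclear and 89 and 80 cytoplasmic minutes. Nuclear half-life was the longer of the pair in 6136 of 11837 genes and cytoplasmic half-life in 676. Chromatin half-life exceeded export half-life in 3631 of 12182 genes and fell short of it in 189, and without degradation calls in 3432 and 142 of 11150. These 2 counts rested on both replicates, because replicate 1 alone gave 3839 and 1410 and replicate 2 alone 7781 and 269. Polysome loading was faster than cytoplasmic loss in 5191 of 11094 genes and slower in 57, the latter rising to 345 without replicate 2 and 300 without replicate 1.

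Genes in this and the next paragraph were ranked by their mean log2 half-life over both replicates, among those with intervals of at most 4-fold in both. The longest chromatin half-lives in K562 included CPNE7 (hg38 chromosome 16, 89575768 to 89597246) with 640 (520 to 790) and 880 minutes (680 to 1100), and IQGAP1, a cytoskeletal scaffold gene, with 530 (510 to 580) and 530 minutes (500 to 580). The shortest with a mode inside its interval was SOCS3, a cytokine signalling inhibitor gene (hg38 chromosome 17, 78356778 to 78360077), with 5.7 (4.6 to 7) and 7.1 minutes (5.5 to 9.2), followed by NOP16 with 7.8 and 8.4 minutes and CISH with 12 and 10 minutes. Export was slowest for SCG3 (1200 and 1300 minutes) and the lysozyme gene LYZ (1100 and 1200), and fastest for TXNIP, encoding a regulator of redox and glucose uptake, with 0.92 (0.43 to 1.3) and 0.77 minutes (0.35 to 1.1). ZEB2 (1.3 and 1.2 minutes) and the cyclin gene CCNL1 (1.6 and 1.1 minutes) also had short export half-lives. These come from the authors' model without nuclear degradation, and ZEB2 carried the authors' call of nuclear degradation. In the cytoplasm, ACADVL, a mitochondrial fatty acid oxidation gene, ranked longest with 2200 and 470 minutes. SGSM3 had 960 and 860, above ACADVL in replicate 2. The shortest cytoplasmic half-lives belonged to the histone gene H4C3 with 2.3 (1.2 to 3.2) and 1.8 minutes (0.81 to 2.7), the endoplasmic reticulum chaperone gene CANX with 3.5 and 2.3, the chromatin remodeller gene CHD4 with 3 and 2.7, the stress response gene IER3 with 3.5 and 2.8, and the fatty acid desaturase gene SCD with 4.8 and 2.3. RPL21, a ribosomal protein gene (hg38 chromosome 13, 27251309 to 27256691), had the longest whole-cell half-life, 2600 (2300 to 2900) and 2200 minutes (1900 to 2500), and ALAS2, the erythroid heme synthesis enzyme gene, had 2200 and 1600 minutes. Whole-cell half-lives were shortest for SOCS3 (12 and 16 minutes), the lymphocyte activation gene CD69 (19 and 16) and CISH (18 and 17).

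In NIH-3T3, Fn1 had one of the longest chromatin half-lives, 910 (900 to 950) and 1600 minutes (1500 to 1600), next to the laminin gene Lama2 (800 and 2200) and the basement membrane collagen gene Col4a6 (950 and 1600). Hist1h2bp (6.8 and 6.9 minutes), Clec11a (7.5 and 6.5) and Srp9 (6.6 and 9.1) were among the shortest with a mode inside the interval. Export half-life was longest for the carboxypeptidase gene Cpe (820 and 510 minutes) and the class I antigen gene B2m (900 and 280), and short for the translation initiation gene Eif4a2, 1.9 (0.87 to 2.6) and 1.3 minutes (0.58 to 1.8), Hmga2 (2.8 and 2.4), Rps12 (2.5 and 2.7) and the stress transcription factor gene Atf4 (3.2 and 3.5), of which Eif4a2 and Rps12 carried the degradation call. Rps12, with 390 (350 to 430) and 440 minutes (410 to 490), and Rpl12, with 440 and 390, were among the longest in the cytoplasm. Hist1h2an (1.1 and 1 minutes), the ubiquitin gene Ubb (1.4 and 0.91) and the cytolinker gene Plec (1.7 and 1.9) were among the shortest there. In the whole cell, the smooth muscle actin gene Acta2 lasted longest, 2600 (2000 to 3300) and 2400 minutes (1900 to 3100), ahead of Tpt1 (1500 and 1400), Rps23 (1400 and 1400) and Rps15 (1300 and 1400). Eid3 (10 and 9.8), Arrdc3 (12 and 9.8) and the stress gene Ddit3 (13 and 12) were shortest. Histone, ribosomal protein and gamma globin genes have near-identical copies, and how reads shared between copies were assigned was not stated.

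Gene lists were then compared with all other genes of the same line. Transcripts of cytosolic ribosomal proteins were among the most stable, with a median whole-cell half-life of 677 minutes (740 and 590) against 206 for other genes in K562 (79 genes) and 527 minutes (530 and 540) against 110 in NIH-3T3 (78 genes). They also entered polysomes fast, at 1.34 against 10.3 minutes in K562 and 1.39 against 10.2 in NIH-3T3, and had long cytoplasmic half-lives (198 against 81.8 and 68.4 against 35.8 minutes). RPL12 had the longest cytoplasmic half-life of the list in K562 (630 and 450 minutes), and RPL13A one of the fastest polysome loadings (0.28 and 0.26 minutes). Similar values occurred elsewhere, such as 0.25 minutes for Actb polysome loading in both NIH-3T3 replicates. The RPL13A values may therefore be limits of the fit rather than measured sizes. On chromatin the lines differed in sign: the list median was 31.0 against 50 minutes in K562, below other genes, and 124 against 61.3 in NIH-3T3, above them. Each of these had a permutation p of 2e-05, the smallest that 100000 permutations can give and an adjusted p of 7.34e-05. Altogether 101 of 156 tests passed in K562 (52 longer, 49 shorter) and 84 of 156 in NIH-3T3 (38 longer, 46 shorter). With narrow intervals these were 50 longer and 23 shorter of 137 in K562, and 43 and 32 of 155 in NIH-3T3. Polysome loading was the least precise half-life. Its intervals were at most 4-fold for 9.59% and 20.1% of values in K562 and 36.3% and 41.9% in NIH-3T3. List values for this step therefore rest mostly on wide intervals.

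Further lists had long whole-cell half-lives, each at an adjusted permutation p of 7.34e-05 in both lines unless given. Nuclear-encoded respiratory chain genes had whole-cell medians of 583 against 206 minutes in K562 and 435 against 110 in NIH-3T3, with COX7A2 at 1700 and 1600 minutes in K562. They stayed long in the nuclear fraction too (167 against 78.7 and 267 against 76.9 minutes). Proteasome subunits had whole-cell medians of 535 against 208 and 275 against 110 minutes, with PSME1 at 1100 and 1000 minutes in K562. Translation factors had 465 and 225 minutes in the 2 lines. Glycolysis genes had 552 (adjusted p = 0.000255) and 328 minutes, aminoacyl-tRNA synthetases 499 (0.000367) and 277 (0.000255), chaperones 368 (0.00211) and 214 (0.000424), and mitochondrial ribosomal proteins 345 (0.000139) and 163 (0.00167). Core spliceosome genes had 410 and 165 minutes (adjusted p = 0.0124 in NIH-3T3), DNA replication genes 317 (0.0062) and 169 (0.00539), and nuclear pore and mRNA export genes 337 in K562 (0.00253) and 130 in NIH-3T3 (0.299, not called). Erythroid genes were long-lived in K562, with 341 against 208 minutes (40 genes, adjusted p = 0.00462), and 11 measured in NIH-3T3 had 183 minutes (adjusted p = 0.136, not called). Whole-cell half-life did not pass for mitotic genes (270 minutes, adjusted p = 0.103, and 103 minutes, 0.728), ribosome biogenesis (274, 0.0741, and 135, 0.172), nuclear RNA decay machinery (187, 0.695, and 87.2, 0.276), cytoplasmic mRNA decay machinery (216, 0.841, and 99.5, 0.614), the ATF4 program (258, 0.368, and 94.3, 0.504) or RNA polymerase II and Mediator (204, 0.927, and 114, 0.804). All of these but RNA polymerase II and Mediator (8.12 against 10.2 minutes, adjusted p = 0.277) loaded onto polysomes faster than other genes in K562, from 3.44 minutes for ribosome biogenesis to 5.91 for cytoplasmic mRNA decay machinery.

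Immediate early and AU-rich transcripts had whole-cell medians of 36.1 against 209 minutes in K562 (42 genes) and 28.1 against 110 in NIH-3T3 (58 genes), and were also short on chromatin (19.5 against 50 and 18.0 against 61.8 minutes) and in the cytoplasm (12.5 against 82.4 and 10.3 against 36), all at an adjusted permutation p of 7.34e-05. Within the list, IER2 had the shortest cytoplasmic half-life in K562 (0.99 and 1.5 minutes) and Egr1 in NIH-3T3 (2.2 and 3.4 minutes), while JUND and FOSB lay at the long end in K562 with whole-cell values of 100 and 110 and of 110 and 300 minutes. The C2H2 zinc-finger family, mostly transcriptional repressors, had 74.2 against 215 whole-cell minutes in K562 (391 genes) and 42.4 against 110 in NIH-3T3 (346 genes), at the same adjusted p. Unlike most lists it loaded onto polysomes more slowly than other genes, at 16.6 against 10 and 14.0 against 10.1 minutes. p53 target genes had whole-cell medians of 120 (adjusted p = 0.0417) and 71.0 minutes (0.0402), and histone and DNA modifiers 150 (0.039) and 78.5 minutes (0.0136).

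Replication-dependent histone transcripts combined the fastest polysome loading of any list in K562 (1.05 against 10.3 minutes) with short cytoplasmic half-lives, 25.6 against 82.4 minutes in K562 (56 genes) and 8.74 against 36 in NIH-3T3 (62 genes), each at an adjusted permutation p of 7.34e-05. H4C3 in K562 and Hist1h2an in NIH-3T3 were at the short end. Splicing regulators had long cytoplasmic half-lives, 142 against 82.0 minutes in K562 (50 genes, adjusted p = 0.000535) and 63.7 against 35.9 in NIH-3T3 (7.34e-05), whereas their export half-life, from the model without nuclear degradation, was short in NIH-3T3 (14.0 against 34 minutes, 7.34e-05). There 24 of 46 assessed genes of the list carried the degradation call, and 19 of 42 did in K562. Export of the list was not called in K562 (32.6 against 42.2 minutes, adjusted permutation p = 0.196). Genes with the degradation call had longer cytoplasmic medians than genes without it in both lines. The list was not tested without them, for export or for cytoplasmic half-life. In the K562 nucleus splicing regulators were shorter-lived than other genes (58.4 against 78.9 minutes, adjusted p = 0.0269), a call that turned to a log2 difference of 0.08 with the posterior mean. HNRNPA3 and RBM3 (470 and 350 minutes) led their K562 cytoplasmic values, and Clk1 (4.4 and 4.6 minutes) had one of the shortest export half-lives of the list in NIH-3T3, also with the call.

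Fibroblast and matrix genes stood out by their distribution over compartments. In NIH-3T3 they had chromatin medians of 267 against 61.2 minutes (59 genes) and nuclear medians of 368 against 77 (58 genes) beside a cytoplasmic median of 10.2 against 36 minutes (57 genes), all at an adjusted permutation p of 7.34e-05. The calcium-binding protein gene S100a6 (0.8 and 0.78 minutes) and the galectin gene Lgals1 (1.7 and 1.2) had the shortest cytoplasmic half-lives of the list. Where measured in K562 the same genes were also long on chromatin (139 against 50 minutes, 29 genes) and in the nucleus (203 against 78.7, 38 genes), and short in the cytoplasm (42.4 against 82.2 minutes, 31 genes, adjusted p = 0.00461). Polysome loading differed in sign, with 29.7 against 10.2 minutes in K562 (27 genes, adjusted p = 0.00108) and 4.43 against 10.2 in NIH-3T3 (56 genes, 7.34e-05). Cholesterol biosynthesis genes, whose products sit mostly in the endoplasmic reticulum, also had short cytoplasmic half-lives (39.0 against 82.2 minutes, adjusted p = 0.0046, and 19.2 against 36, 0.00105).

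**Figure D2:**
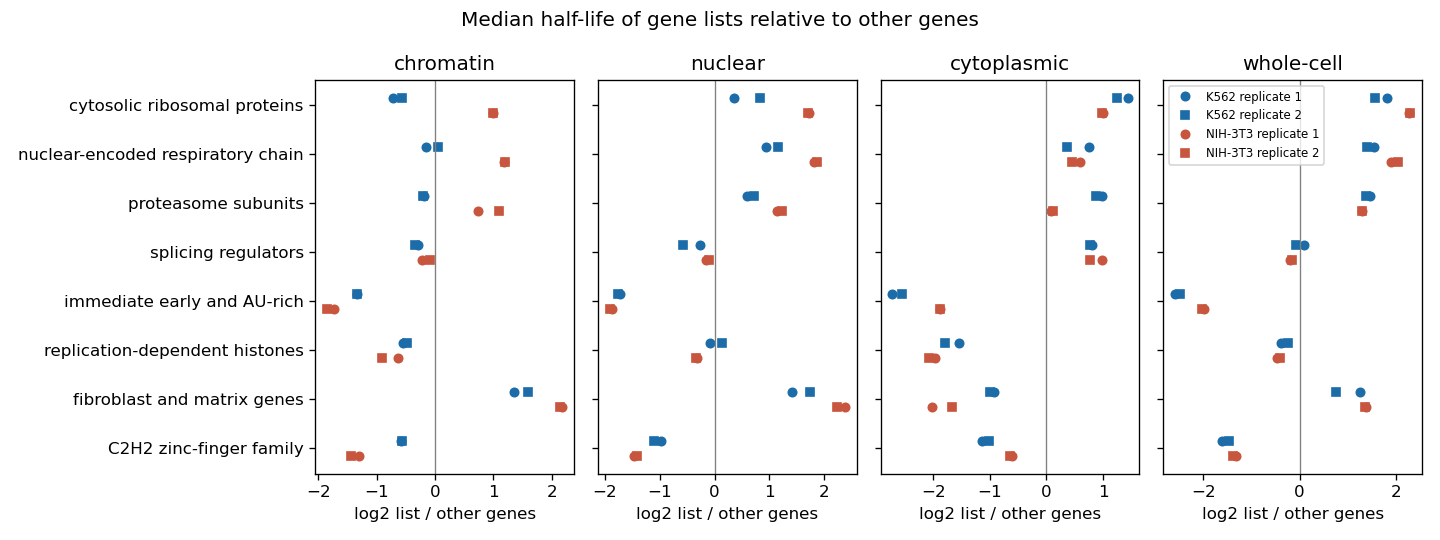
Log2 of the list median over the median of other genes for 8 gene lists and 4 half-lives (chromatin, nuclear, cytoplasmic, whole-cell), with 1 point per cell line and replicate and a vertical line at 0. Ribosomal protein genes lie left of 0 on chromatin in K562 (mean of replicates -0.69) and right of it in NIH-3T3 (1.02), and immediate early and AU-rich genes lie left of 0 in every panel.

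Next, K562 was compared with NIH-3T3 gene by gene. The 2 lines differ in species, cell type and library batch at once, and these cannot be told apart in this contrast. Whole-cell half-lives were mostly longer in K562. SRP9, encoding a subunit of the signal recognition particle (hg38 chromosome 1, 225777813 to 225790466), had 1400 and 1100 minutes in K562 against 27 and 23 in NIH-3T3, a log2 difference of 5.64 (SE 0.18, limma adjusted p = 0.0033). The centromere protein gene CENPW (960 and 1300 against 34 and 36) and GNG5, a G protein subunit gene (1700 and 1200 against 62 and 56, log2 4.60) were also among the largest differences. Among landmark genes, SRSF3 (270 and 250 against 41 and 46 minutes, log2 2.58), the mitotic cyclin gene CCNB1 (300 and 290 against 80 and 83, log2 1.86) and the p53 regulator gene MDM2 (150 and 160 against 44 and 41, log2 1.87) were longer in K562. Longer-lived in NIH-3T3 were the smooth muscle gene TAGLN (110 and 77 against 850 and 1200, log2 -3.46, SE 0.29, adjusted p = 0.0038), the matrix gene EFEMP2 (50 and 47 against 620 and 410, log2 -3.38) and the collagen receptor gene DDR2 (45 and 40 against 290 and 280, log2 -2.75). By limma 5369 of 8913 genes were longer in K562 and 451 in NIH-3T3, with a median log2 difference of 0.84, and after centring each table on its median 1618 and 2346. MYC (27 and 28 against 21 and 21) and GAPDH (1100 and 1000 against 690 and 690) were longer in K562 by log2 0.39 and 0.60 as measured, but after centring these values were -0.58 and -0.36. Without either NIH-3T3 replicate limma called 0 genes, while 4487 (without replicate 1) and 4550 (without replicate 2) had an unadjusted p under 0.05.

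Cytoplasmic half-lives differed most in level. VPS33B, a vesicle sorting gene, had 140 and 120 minutes in K562 and 1.4 and 1.5 in NIH-3T3 (log2 6.48, SE 0.20, limma adjusted p = 0.007), the endocytic receptor gene LRP1 63 and 50 against 1 and 1.2 (log2 5.68), and RPL38 230 and 140 against 2.9 and 4.8 (log2 5.59). The matrix genes COL1A1 (57 and 66 against 4 and 2.3, log2 4.34) and FN1 (29 and 23 against 1.6 and 2, log2 3.85), the helicase gene DDX3X (140 and 150 against 15 and 14, log2 3.32) and ACTB (77 and 35 against 6.8 and 6.5, log2 2.97, adjusted p = 0.011) were longer in K562. Fewer transcripts lasted longer in the NIH-3T3 cytoplasm, among them DAD1 (11 and 10 against 130 and 100, log2 -3.44), NDUFA6 (30 and 34 against 260 and 230, log2 -2.94) and IER2 (0.99 and 1.5 against 5.1 and 5.9, log2 -2.17, adjusted p = 0.0087). TFPI was at the bound of 6900 minutes in both NIH-3T3 replicates. By limma 4853 of 9087 genes were longer in K562 and 189 in NIH-3T3, with a median log2 difference of 1.11, and 894 and 1273 after centring. Counts fell to 2286 and 65 without K562 replicate 2, and limma called 0 genes without K562 replicate 1 (4537 with an unadjusted p under 0.05), NIH-3T3 replicate 1 (4422) or NIH-3T3 replicate 2 (4151).

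Chromatin half-lives were more often longer in NIH-3T3. RPLP0, a ribosomal stalk protein gene (hg38 chromosome 12, 120196686 to 120201235), stayed on chromatin for 19 and 32 minutes in K562 and 280 and 490 in NIH-3T3 (log2 -3.91, SE 0.37, limma adjusted p = 7.1e-14). DDX3X (22 and 24 against 110 and 140, log2 -2.43), the intermediate filament gene VIM (72 and 69 against 290 and 480, log2 -2.40) and ACTB (110 and 140 against 370 and 630, log2 -1.96) had the same direction, and IER2 the opposite (36 and 43 against 13 and 17, log2 1.40, adjusted p = 0.0014). For chromatin, limma took each gene's variance almost wholly from all genes together (prior degrees of freedom 72.3, against 1.48 to 3.77 for other half-lives). The small p-values here rest on that shared variance more than on a gene's own replicates. They are not comparable with the p-values of other half-lives. The largest fitted differences involved the bound, as for TTYH1 and QRFP, both at 6900 minutes in K562. By limma 940 of 9380 genes were longer in K562 and 2686 in NIH-3T3, at a median log2 of -0.35, and 2423 and 2515 after centring. Without centring, the median log2 difference was -0.57 without NIH-3T3 replicate 1 and -0.14 without NIH-3T3 replicate 2. The counts were 216 and 539 without K562 replicate 1 and 152 and 760 without K562 replicate 2. Limma called 0 without NIH-3T3 replicate 1 (4595 with an unadjusted p under 0.05) or replicate 2 (3799).

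Nuclear half-lives were evenly divided, with 1882 of 9466 genes longer in K562 and 1892 in NIH-3T3 by limma at a median log2 of 0. GNG5 (800 and 640 against 15 and 26 minutes, log2 5.18), the lectin receptor gene CLEC2D (370 and 430 against 16 and 14, log2 4.74) and TMEM126A (330 and 360 against 18 and 15, log2 4.39) stayed longer in the K562 nucleus. KXD1 (33 and 41 against 610 and 640, log2 -4.09), SNX22 (29 and 32 against 460 and 620, log2 -4.13) and the proteasome assembly gene PSMG4 (20 and 21 against 340 and 280, log2 -3.91) stayed longer in that of NIH-3T3. For export, RPS12 (120 and 240 against 2.5 and 2.7 minutes, log2 6.03, SE 0.50, limma adjusted p = 0.027), SRP9 (140 and 320 against 4.9 and 5.6, log2 5.34) and the splicing factor gene SRRM2 (170 and 300 against 7 and 10, log2 4.75) were slower in K562. The copper chaperone gene ATOX1 (6.5 and 6.1 against 720 and 1500, log2 -7.37, adjusted p = 0.018), PSMG4 (2.2 and 1.7 against 270 and 160, log2 -6.75) and the cold-shock gene RBM3 (2.2 and 1.9 against 110 and 53, log2 -5.22) were slower in NIH-3T3. Of these, RPS12, SRP9 and SRRM2 carried the degradation call in NIH-3T3 and PSMG4 and RBM3 in K562, so of the 6 only ATOX1 remained among genes without the call. Of the 20 genes with the largest export differences 6 remained. Of 9135 genes limma called 398 slower to export in K562 and 420 in NIH-3T3, at a median log2 of 0.33, or 909 and 1396 after centring. The balance leaned to slower export in K562 by intervals apart (1637 and 502), with the replicate block (948 and 652) and with narrow intervals (628 and 383 of 6649). The median log2 difference was 0.62 without NIH-3T3 replicate 1 and 0.006 without NIH-3T3 replicate 2. The median of 0.33 thus rested mainly on NIH-3T3 replicate 2. Leaving out any one replicate left 0 limma calls for nuclear half-life (3281 to 4296 with an unadjusted p under 0.05) and for export (1066 to 3709). For polysome loading 37 and 33 of 8358 genes passed limma, the largest differences being values at or near 6900 minutes, such as CD109 and NDUFS8 in K562. That count was 0 with the posterior mean (887 at an unadjusted p under 0.05), 0 for genes with modes inside their intervals (891), 0 with the replicate as a block (741) and 0 without any one replicate (397 to 1768), so single genes are not interpreted.

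Gene lists also moved between the lines relative to all genes, as tested with limma's camera. Transcripts of cytosolic ribosomal proteins spent less time on chromatin in K562 than in NIH-3T3, by a median log2 of -1.39 relative to all genes (78 genes, adjusted p = 3.16e-12, or adjusted p = 0.983 with an estimated correlation), with 3 genes longer in K562 and 56 in NIH-3T3, and 3 and 58 adjusted over the list alone. Proteasome subunits (-0.96, 35 genes, adjusted p = 1.45e-05, 1 and 27 genes, 1 and 29 adjusted over the list alone) and translation factors (-1.04, 43 genes, adjusted p = 0.000159, 0 and 28 genes, the same adjusted over the list alone) went the same way, each at 0.983 with an estimated correlation. Nuclear-encoded respiratory chain genes did too, at -0.96 (61 genes, 5 and 39 genes, 5 and 43 adjusted over the list alone, adjusted p = 0.00012, or 0.983 with an estimated correlation). In the cytoplasm proteasome subunits were longer in K562 by 0.90 beyond the median of all genes (adjusted p = 0.00824, 28 and 1 of 35, 29 and 1 adjusted over the list alone). With an estimated correlation this and the next list were at 0.983. The immediate early and AU-rich list exceeded its NIH-3T3 values by less than all genes did (median log2 0.31, or -0.80 relative to all genes, adjusted p = 0.000112, 8 and 3 of 48 genes, 2 and 1 adjusted over the list alone). Whole-cell half-lives of mitotic genes (0.49, adjusted p = 0.011, 43 and 0 of 50 genes, 44 and 2 adjusted over the list alone) and DNA replication genes (0.45, adjusted p = 0.0202, 44 and 0 of 52, the same adjusted over the list alone) were longer in K562 beyond all genes, each at 0.983 with an estimated correlation. Export of histone and DNA modifiers was slower in K562 (0.84, adjusted p = 0.000264, 6 and 1 of 59, 20 and 2 adjusted over the list alone, or 0.983 with an estimated correlation). For polysome loading, fibroblast and matrix genes were slower in K562 (3.46, 26 genes, adjusted p = 2.34e-07) and replication-dependent histones faster (-1.55, 41 genes, adjusted p = 0.000122), although single genes of either list gave 0 limma calls over all genes, and 11 and 0 for the former and 1 and 3 for the latter adjusted over the list alone. With an estimated correlation both were at 0.983. In all 47 list and half-life pairs passed camera, and 0 passed with an estimated correlation, where each had an adjusted p of 0.983.

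Nuclear degradation was the last comparison, and asks which transcripts the authors' model placed under decay before export. TRA2B, encoding a splicing activator (hg38 chromosome 3, 185915906 to 185938136), had in K562 a nuclear degradation half-life of 26 and 22 minutes. HNRNPH1 (80 and 80 minutes), the chromatin remodelling gene SMARCE1 (26 and 18) and GRHPR (26 and 22) were also among the clearest calls. In NIH-3T3 these were Bclaf1 (66 and 66 minutes), Fubp1 (22 and 31), Rps12 (46 and 46), Rps24 (46 and 66), Vmp1 (38 and 55) and Eif4a2 (18 and 26). The call, a Bayes factor of at least 100 in both replicates, held for 371 of 11409 assessed genes in K562 (3.25%) and 509 of 11667 in NIH-3T3 (4.36%). Replicate 1 alone gave 601 and 853 genes, and replicate 2 alone 818 and 858. Splicing regulators were called most often, in 19 of 42 genes in K562 (45.2%, Fisher's exact test, adjusted p = 2.00e-16) and 24 of 46 in NIH-3T3 (52.2%, adjusted p = 1.12e-19). Nuclear RNA decay machinery (6 of 26, 23.1%, adjusted p = 0.0095) and cytosolic ribosomal proteins (9 of 70, 12.9%, adjusted p = 0.0281) passed in NIH-3T3, against 3 of 26 (adjusted p = 0.208) and 2 of 30 (0.663) in K562. The difference between the lines was not tested.

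Among 8579 genes assessed in both lines, 53 were called in both, where 16.1 would be shared by independent lists of 321 and 430 genes (odds ratio 4.13, Fisher's exact test, p = 5.31e-15). They included the RNA-binding protein genes DDX5, FUBP1, HNRNPDL, HNRNPH1, HNRNPH3, HNRNPU, RBM39, SRSF5 and TRA2B, the nuclear matrix protein genes SAFB and SAFB2, the exosome subunit gene EXOSC1, the nonsense-mediated decay gene UPF3A, the microRNA processing gene DGCR8 and the cold-inducible gene CIRBP. Called genes in K562 had median nuclear half-lives of 41 and 46 minutes against 73 and 85 for genes without the call, export ones of 9.2 and 6.8 against 38 and 47, cytoplasmic ones of 170 and 160 against 85 and 74, and whole-cell ones of 140 and 120 against 210 and 200. In NIH-3T3 these were 45 and 48 against 80 and 80, 25 and 15 against 42 and 27, 86 and 81 against 36 and 34, and 72 and 74 against 110 and 110 minutes.

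Relations between steps were described across genes, which are not independent replicates, and half-lives fitted to the same samples share error. Genes slow on chromatin were slow in the nucleus, with Spearman's rho of 0.767 and 0.740 in K562 and 0.874 and 0.877 in NIH-3T3. Nuclear RNA includes RNA on chromatin, and whole-cell RNA includes nuclear and cytoplasmic RNA. Relations of a part with its whole are therefore partly built in. Between the successive steps of chromatin and export, rho was lower (0.522 and 0.479 in K562, 0.657 and 0.425 in NIH-3T3). Nuclear and cytoplasmic half-lives were nearly unrelated (0.08 and 0.04 in K562, -0.02 and 0.01 in NIH-3T3). Whole-cell half-life followed nuclear half-life (0.698 and 0.741, 0.849 and 0.861) more than cytoplasmic half-life (0.466 and 0.348, 0.145 and 0.181). Polysome loading was related to cytoplasmic half-life in NIH-3T3 (0.311 and 0.299) and hardly in K562 (0.02 and 0.03), but among genes with narrow intervals the values were 0.451 and 0.405 in NIH-3T3 and 0.292 and 0.156 in K562 (1068 and 2284 genes). Among gene features in K562, exon number had the highest rho, with chromatin half-life (0.366 and 0.335) and with cytoplasmic half-life (0.234 and 0.273). Gene length went with chromatin half-life (0.255 and 0.228), and spliced length (-0.18 and -0.18) and 3' UTR length (-0.149 and -0.155) went against whole-cell half-life. No p-value was computed for these 30 relations of features or for those between steps.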

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

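In this part, the scale factor test and the use of narrow-interval values as tests were chosen only after the results were seen, the limma tests of ratios were added after the tables were first examined, the prediction for the chromatin libraries was written before its value was computed, and the camera tests were planned.

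The balance between nucleus and cytoplasm differed between the lines in a direct test of the difference. The log2 ratio of nuclear over cytoplasmic half-life was higher in NIH-3T3 for 3492 of 9087 genes and in K562 for 365 (limma, adjusted p under 0.05), with medians of -0.36 and 0 in the K562 replicates and 0.94 and 1.04 in those of NIH-3T3. The level of cytoplasmic half-lives behind it was weighed against 3 explanations. A single scale factor between the tables of the lines would shift nuclear and cytoplasmic half-lives alike and leave their ratio unchanged. The median log2 difference (K562 minus NIH-3T3) was larger by 1.11 for cytoplasmic than for nuclear half-life, which argues against it. This value restates the difference in ratios and is not separate evidence. A factor that acts on the cytoplasmic values of 1 line only was not tested. Poorly determined genes are argued against by the genes with credible intervals of at most 4-fold in all 4 tables, whose median cytoplasmic difference was 1.12. A difference between library batches, between species or between the cell types stays open, because each line is its own species and set of libraries, and the difference of 1.11 cannot be told apart into these.

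The log2 ratio of chromatin over export half-life also differed between the lines by a direct test, being higher in NIH-3T3 for 476 of 9135 genes and in K562 for 175 (limma, adjusted p under 0.05). Its medians were 0.16 and 0 in the K562 replicates and 0.28 and 1.41 in those of NIH-3T3, so the lines stood apart mainly in NIH-3T3 replicate 2. Both half-lives in this ratio shifted in opposite directions between the NIH-3T3 replicates (chromatin median log2 0.45, export -0.55, replicate 2 minus replicate 1). Wide credible intervals are argued against as the source of that shift, since it was -0.58 for export among genes with intervals of at most 4-fold. The nuclear half-life did not shift between these replicates (median log2 0, also with narrow intervals). Export half-life is that of nuclear RNA released from chromatin. With nuclear half-life unchanged, the opposite shifts of chromatin and export are therefore not 2 independent results. Per the labels, the NIH-3T3 chromatin libraries carry other sample codes than the other fractions of that line, and what the codes stand for is not stated. If they had another origin, the replicate differences of chromatin and export half-life might be more strongly opposed in NIH-3T3 than in K562. Spearman's rho was -0.35 against -0.24, a difference of -0.11 that lay between the 2 bounds set in advance, so this explanation remains undecided, and no biological explanation was tested.

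For the log2 ratio of cytoplasmic over polysome loading half-life limma called 0 of 8358 genes (1754 with an unadjusted p under 0.05), at a median difference of 1.24. Transcripts of cytosolic ribosomal proteins lay on opposite sides of other genes on chromatin in the 2 lines, with a median log2 difference relative to all genes of -1.39 (camera, adjusted p = 0.983 with an estimated correlation). Fibroblast and matrix genes did so for polysome loading, at 3.46 (camera, adjusted p = 0.983 with an estimated correlation), where the K562 values included COL1A1 with a mode of 6900 minutes outside its own interval.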

How the results depend on the processing

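The mode-inside-interval and export-without-degradation alternatives were chosen after seeing the data; the others were set before. Of 185 list calls within lines, cameraPR kept 161, matched random lists 158, the posterior mean 173, modes inside intervals 184 and narrow intervals 140 with 25 lost. Single replicates kept 168 and 169. The calls that reversed were splicing regulators in the K562 nucleus with the posterior mean (log2 0.0805) and histone and DNA modifiers in polysome loading with narrow intervals (0.170 in K562, 0.0536 in NIH-3T3); the cause was not tested. Of 120 genes named between lines, 100 passed with the posterior mean, 99 with the block, 92 with trend and robust settings, 111 after centring and 120 with a pseudocount. With modes inside intervals 68 passed and 9 missed the threshold. The rest had a mode outside its interval in some table and could not be tested there. With narrow intervals 50 passed, and the rest had a wider interval in some table. Without K562 replicate 1 or 2, 35 and 50 passed, and without either NIH-3T3 replicate all 120 missed the threshold; the lone sample is then assumed to vary like the others. Of 47 list calls between lines, 45 passed with the posterior mean, 40 with the block, 37 after centring, 36 to 42 without 1 replicate, and 0 with an estimated correlation. The block was of little use, since deviations of equally numbered replicates correlated at -0.05 to 0.02.

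Replicate rho with narrow intervals was 0.909 (chromatin), 0.939 (nuclear), 0.927 (cytoplasmic), 0.504 (polysome loading) and 0.948 (whole-cell) in K562, and 0.947, 0.952, 0.900, 0.670 and 0.953 in NIH-3T3. With the posterior mean it was 0.871 (K562 nuclear), 0.528 (K562 polysome loading), 0.916 (NIH-3T3 nuclear), 0.814 (NIH-3T3 cytoplasmic) and 0.568 (NIH-3T3 polysome loading). With modes inside intervals it was 0.917 (K562 nuclear), 0.833 (K562 cytoplasmic), 0.899 (K562 whole-cell) and 0.922 (NIH-3T3 nuclear). With 1% trimmed it was 0.914 (K562 nuclear), 0.535 (K562 polysome loading), 0.898 (K562 whole-cell) and 0.921 (NIH-3T3 nuclear).

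By a 2-fold criterion, K562 counts were 1083 (export over chromatin), 2133 (cytoplasmic over nuclear) and 254 (polysome loading over cytoplasmic), and NIH-3T3 counts 2415 (chromatin over export), 116 (export over chromatin) and 276 (polysome loading over cytoplasmic). Single replicates gave 153 to 360 for K562 polysome loading over cytoplasmic. In NIH-3T3 they gave 3839 to 7781 for chromatin over export, 269 to 1410 for export over chromatin, 300 to 345 for polysome loading over cytoplasmic and 945 to 1119 for cytoplasmic over nuclear. Single replicates gave 601 to 818 degradation calls in K562 and 853 to 858 in NIH-3T3.

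Between lines, export calls numbered 2305 after centring, 1600 with the block, 2139 by intervals apart and 543 without degradation-called genes, where fewer genes were tested. Nuclear calls numbered 2336 with the block, and cytoplasmic calls 2167 after centring. Polysome loading calls numbered 0 with the posterior mean, 0 with modes inside intervals, 0 with the block, 3 with trend and robust settings, 4 with narrow intervals and 222 by intervals apart. Without 1 replicate limma called 0 to 912 genes for chromatin, 0 to 2351 for cytoplasmic, 0 to 4353 for whole-cell, and 0 to 0 for nuclear, export and polysome loading, where 397 to 4296 had an unadjusted p under 0.05.

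Mean rho of chromatin with export in K562 was 0.446 (posterior mean) and 0.452 (narrow intervals). For nuclear with cytoplasmic it was 0.0256 and 0.0873 in K562 and -0.0415 and 0.0215 in NIH-3T3. For NIH-3T3 cytoplasmic with whole-cell it was 0.137 and 0.209, and for NIH-3T3 nuclear with whole-cell 0.899 (narrow intervals). Exon number with chromatin had 0.293 (median over transcripts) and 0.377 (narrow intervals), exon number with cytoplasmic 0.283 and gene length with chromatin 0.261 (narrow intervals). Spliced length with whole-cell had -0.182 (narrow intervals) and -0.174 (posterior mean), and 3' UTR length with whole-cell -0.181 (median over transcripts) and -0.142 (posterior mean). The cause of these changes was not tested. With 2 tables per line, neither outlying samples nor other splits of the samples can be tested, and the number of reads behind a value, which limits its precision, is unknown here.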

Other observations

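The use of narrow-interval values as a test in this part was chosen after the result was seen, and so were the list and the test of endoplasmic reticulum genes, whose prediction was written before its value was computed.

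The paired fetal globin genes of K562, whose coding sequences are nearly identical, had different half-lives. HBG1 (hg38 chromosome 11, 5248079 to 5249859) had nuclear half-lives of 270 (260 to 280) and 310 minutes (300 to 310) and cytoplasmic ones of 69 (66 to 73) and 66 (63 to 70). HBG2 had 930 and 1100 nuclear and 23 and 12 cytoplasmic minutes, with a longer annotated span (5253190 to 5505605). How reads shared by the 2 genes were assigned is not stated. Among single genes of nuclear RNA surveillance, cytoplasmic half-lives in K562 were 450 and 480 minutes for PABPN1, a nuclear poly(A)-binding protein gene, 250 and 200 for the exosome nuclease gene EXOSC10, 120 and 110 for ZFC3H1 and 89 and 110 for DIS3. In NIH-3T3 these were 180 and 140, 47 and 49, 80 and 81, and 64 and 55 minutes. The list of nuclear RNA decay machinery was not called for K562 cytoplasmic half-life (120 against 82.0 minutes, adjusted permutation p = 0.0865). OGT, encoding a nutrient-sensing glycosyltransferase, stayed on chromatin for 170 and 200 minutes in K562 and 100 and 120 in NIH-3T3 and was then exported in 31 and 15 minutes in either line.

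Whole-cell half-life was not the sum of its parts. The median ratio of whole-cell half-life over the sum of nuclear and cytoplasmic half-lives was 1.14 and 1.09 in the K562 replicates and 0.877 and 0.904 in those of NIH-3T3.

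Fibroblast and matrix genes had short cytoplasmic and long nuclear half-lives, and a candidate explanation is that mRNA bound to the endoplasmic reticulum was collected with the nuclei. If so, other transcripts translated there should show the same, and a list of such genes without any fibroblast, matrix or cholesterol gene was compared with random genes matched on whole-cell half-life. Their log2 ratio of nuclear over cytoplasmic half-life lay above that of matched genes by 4.11 in K562 (80 genes) and by 2.86 in NIH-3T3 (83 genes). Each had a permutation p of 2e-05, the smallest possible. Their median nuclear and cytoplasmic half-lives were 364 and 19.0 minutes in K562 (other genes 77.5 and 82.5) and 373 and 10.9 in NIH-3T3 (other genes 76.5 and 36.2). Wide intervals are argued against, as fibroblast and matrix genes stayed below other genes by a log2 of -1.98 in the NIH-3T3 cytoplasm among narrow-interval genes. The values are compatible with the candidate explanation, but slow release of these transcripts from the nucleus itself was not tested and stays open. The same order was not limited to transcripts of matrix or secreted proteins. In NIH-3T3, Actb, the cytoskeletal actin gene, had 550 and 510 nuclear against 6.8 and 6.5 cytoplasmic minutes. The test does not address such transcripts. Nor does it address the calcium-binding protein gene S100a6 and the galectin gene Lgals1. These had the shortest cytoplasmic half-lives of the fibroblast and matrix list in NIH-3T3. Whether the transcripts of either gene are bound to the endoplasmic reticulum was not tested.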
